A study of Homo sapiens with 10 samples.

How the data were processed

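The series holds 10 samples of 2 human cell lines, TMD8 and OCI-LY10, both of activated B-cell-like diffuse large B-cell lymphoma. Of these, 6 are RNA-seq samples, 3 per line: a control shRNA and 2 shRNAs against STAT3, numbered 10 and 16. Expression of each shRNA was induced with doxycycline at 20 ng/ml for 2 days, per the labels. The other 4 are STAT3 ChIP-seq samples taken 4 h after AZD1480, a JAK inhibitor, or its solvent DMSO. They were not analysed here.

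The authors deposited FPKM values (fragments per kilobase of gene, scaled to library size), with 1 value per gene and library, for OCI-LY10. TopHat, Bowtie2 and the genome build hg19 are named, without versions or roles, per the submitters' processing notes. The tool that computed FPKM, its gene annotation, any scaling between libraries and any use of strand are not given in the sources used here. Libraries were made with a TruSeq RNA kit, per the labels' protocols. The 3 columns of OCI-LY10 were matched to samples by their names. Another 3 columns of per-sample values bear no name, so they were not used, and the 3 TMD8 RNA-seq samples are not analysed here.

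The table has 25277 rows and 25275 symbols. The rows of 2 repeated symbols were summed. Of the symbols, 22534 matched a current gene symbol, 1589 an older symbol or synonym, and 1152 neither. In 26 rows the symbol had become a calendar date, and these rows were not named. No coordinates are given, because the reference table used for names is of another genome build. An FPKM of exactly 0 can be a failed estimate: RPS18, which encodes a ribosomal protein, was listed at 0 in all 3 libraries. Of 91 ribosomal protein and oxidative phosphorylation genes, 1 (RPS18) was listed at 0 in any library. Genes at 0 are therefore described as listed at 0, with a value for each library.

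FPKM gives no total read count. Ratios between libraries of values under 0.1 FPKM gave the relative depth, since the commonest ratio is that of 1 read. Depth relative to shRNA 10 was 1.52 for the control library, from 1168 low values, and 0.73 for shRNA 16, from 1361. Of the low-value ratios, 55.7% and 68.9% lay within 1% of that ratio times a ratio of whole numbers up to 3. Absolute depth is unknown, so no counting interval is given.

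Genes with a mean of at least 1 FPKM over the 3 libraries were tested, 11162 in all, 308 of them small RNA genes. The test was limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, two-sided) on log2(FPKM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. It set the 2 STAT3 shRNA libraries against 1 control library, with 1 residual degree of freedom and 1.64 prior degrees of freedom. The spread of the control is unobserved and was assumed to equal that between the 2 shRNA libraries. The 3 libraries are labelled with different shRNAs, and no condition has a second library. The p-values therefore measure only the spread between the 2 STAT3 shRNA libraries. That spread mixes technical variation with any difference between the 2 shRNAs, and says nothing of replicate cultures of a condition. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Genes changed at least 1.5-fold the same way with both shRNAs were also counted, with no test.

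The 28 gene lists were fixed before the data were examined. They were tested with camera (limma) at an inter-gene correlation of 0.01, with adjustment over the lists. The median log2 ratio of each list was also ranked among 10000 random lists of the same size drawn from 20 bins of mean expression. The effect of the shared control library on correlations was simulated 100 times with unchanged genes.

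The fits over both lines, the TMD8 fit, the difference between lines and the tested comparison of shRNA 16 with shRNA 10 had been planned and were not run, because they need the 3 TMD8 samples. Gene lists and named genes were therefore fitted in OCI-LY10 alone. Named genes were STAT3, 20 fixed genes, the 5 genes up and the 5 down with the largest smaller-of-2-shRNAs change, and up to 4 members per list, the 2 highest and 2 lowest fold changes among the 6 lowest p-values. Genes on the Y chromosome and XIST, 11 of which were tested, are not named. Some genes that the rule names are not reported here. Other genes were chosen after their values were seen, as stated where they appear.

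The test was tried on simulated data for the comparison of STAT3 shRNAs with control in OCI-LY10, over 11162 genes. It recovered 9% of 67 simulated 1.5-fold changes, 79.1% of 67 2-fold changes and 100% of 66 4-fold changes, with 0 unchanged genes called. Far fewer genes were changed in the simulation than were called in the data, so these rates need not hold for the data. When the noise of the control was set to 2 times that of the shRNA libraries, 101 unchanged genes were called. In that setting 23.13% of unchanged genes had an unadjusted p below 0.05 (limma), against 4.1% with equal noise. Counts at an unadjusted p are therefore inflated if the control varies more than was assumed. Alternatives covered the pseudocount, the filter, the scaling, repeated symbols, the variance trend, the thresholds, the set test, and each STAT3 shRNA library left out in turn. Leaving out small RNA genes, genes listed at 0 or genes in both of a pair of lists, and camera with a variance trend, were added after seeing the data.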

Results

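Gene expression was measured by RNA-seq in OCI-LY10, an established human line of activated B-cell-like lymphoma, to ask which genes respond to depletion of the transcription factor STAT3. The 3 libraries analysed comprise 1 labelled control shRNA, 1 with STAT3 shRNA 10 and 1 with STAT3 shRNA 16. Their deposited FPKM values summed to 1230209, 1322165 and 1382655, respectively. Small RNA genes made up 49.0%, 57.8% and 58.1% of these sums. Relative to shRNA 10, sequencing depth was 1.52 times as high in the control library and 0.73 times as high with shRNA 16. Genes listed at 0 numbered 8466 in the control library, 9185 with shRNA 10 and 9463 with shRNA 16. With 1 library per shRNA, the control has no replicate, and the tests treat the 2 STAT3 shRNAs as replicates. The 3 TMD8 RNA-seq samples and the 4 STAT3 ChIP-seq samples of the series are not analysed here.

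STAT3 itself stood at 16.5 FPKM in the control library, 11.1 with shRNA 10 and 10.6 with shRNA 16. The mean of the 2 shRNA libraries was 10.9 FPKM ± 0.397 (SD, n = 2), or 65.8% of control. The log2 change was −0.56 (SE 0.10, limma adjusted p = 0.0465). This call was lost with a pseudocount of 0.1 FPKM (adjusted p = 0.0508) and without the filter on low values (adjusted p = 0.0688). A larger absolute change than that of STAT3 was seen in 44.7% of tested genes.

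The library labelled control shRNA stood apart from both STAT3 shRNA libraries across the transcriptome, and every gene group described here was compared across that gap. Outside small RNA genes, Pearson's r of log2(FPKM + 1) across genes was 0.993 between the 2 STAT3 shRNA libraries, against 0.839 between the control library and either of them. Genes are not independent replicates, so no p is given. At 5 FPKM or more on one side and at most 0.5 on the other, 167 genes were seen in the control library alone and 105 in both STAT3 shRNA libraries alone. Between the 2 STAT3 shRNA libraries, 0 genes met this rule in one direction and 1 in the other. In a check of chromosome-linked genes, 1 of the 3 libraries did not match the others. The comparisons below are therefore between libraries as labelled, and the difference in STAT3 cannot be separated from any other difference between them.

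**Figure D1:**
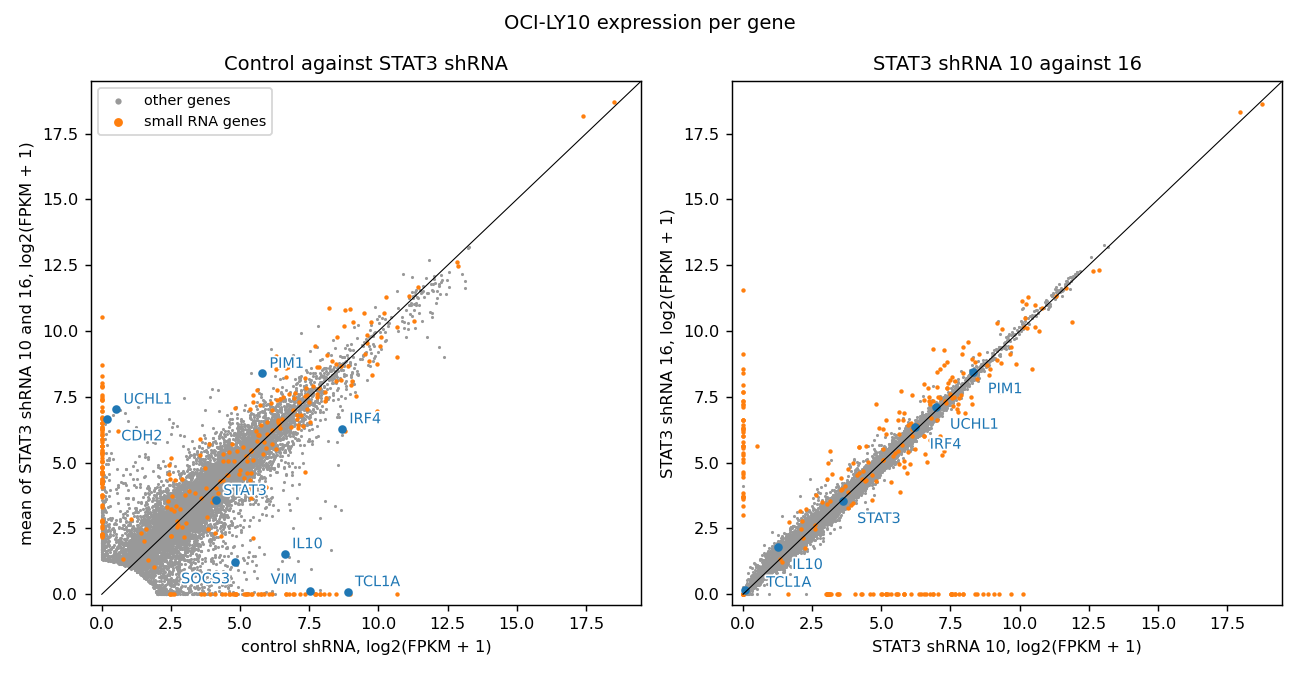
Each point is a tested gene in OCI-LY10, on log2(FPKM + 1) axes, with small RNA genes in orange and genes named in the text in blue. Outside small RNA genes the 2 STAT3 shRNA libraries lie along the diagonal (r = 0.993, right), while the control library against their mean is widely scattered, with genes along both axes (left).

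Between STAT3 shRNA and control, 2263 genes were higher and 1943 lower (limma, adjusted p below 0.05) among 11162 tested. Without the filter on low values 1299 were higher and 2101 lower, and with median-of-ratios scaling 1993 and 2105, so which direction held more genes depends on these settings. With both shRNAs, 2248 genes were at least 1.5-fold higher and 1920 at least 1.5-fold lower, while 26 went opposite ways. Independent lists of the same lengths would share 615 and 438 genes. The log2 ratios of the 2 shRNAs to the control correlated across genes at r = 0.870, where unchanged genes measured against a shared control gave 0.50 in simulation. Their covariance was 1.39, against 0.0174 simulated. The simulation gave the control the spread of the shRNA libraries, so a correlation near 0.50 was fixed by its setting. A shared control library that differs for any reason raises the overlap, the correlation and the covariance. None of them therefore shows an effect of STAT3 depletion.

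Some genes were at high levels in the control library and near 0 in both shRNA libraries, or the reverse. TCL1A, an AKT co-activator expressed in B cells, stood at 474 FPKM in the control library, 0.0396 with shRNA 10 and 0.108 with shRNA 16. Its neighbour in the same family, TCL1B, went from 237 to 0.0979 and 0.134. The intermediate filament gene VIM was at 185 FPKM in the control library against 0.0731 and 0.10. The transcriptional co-regulator gene LMO2 was at 70.3 FPKM against 0.102 and a listed 0. In the other direction, UCHL1, a deubiquitinase of neurons and germinal centre B cells, was at 0.437 FPKM in the control library and 123 and 137 with the shRNAs. The cadherin gene CDH2 was at 0.134 against 94.7 and 107, and the amyloid precursor gene APP at 0.316 against 109 and 112. POU2AF1, a B-cell transcriptional co-activator, was at 2.44 FPKM against 197 and 181. All 8 of these changes passed the test, each with adjusted p = 0.00676. TCL1A, VIM, LMO2 and CDH2 followed from the naming rule. TCL1B, UCHL1, APP and POU2AF1 were chosen after their values were seen, because the part of the rule on the largest changes otherwise returned small RNA genes.

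The small RNA genes named by the rule were MIR4685, SNORD56, SNORD101, SNORD55 and SNORD24, listed at 0 in the control library, and SNORD78, MIR7113, MIR6845 and MIR3689C, listed at 0 in both shRNA libraries. SNORD78 was at 1633 FPKM in the control library, and SNORD56 at 165 with shRNA 10 and 453 with shRNA 16. Such short genes lie inside other genes and their reads cannot be told from those of the host, so these values are uncertain. The ratio of shRNA 16 to shRNA 10 was 1.37 for MIR4685 and SNORD24 and 2.74 for SNORD56, SNORD101 and SNORD55. A single read in each library would give 1.37 and 2 reads against 1 would give 2.74, so these FPKM values are not read as high levels. Without the filter on low values, SNORD56, SNORD101 and SNORD55 also lost their calls (adjusted p = 0.0632, 0.0648 and 0.0655).

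Genes tied to STAT3 signalling went both ways. SOCS3, the feedback inhibitor of JAK-STAT signalling, fell from 27.3 FPKM to 1.36 ± 0.194 (SD, n = 2), a log2 change of −3.59 (SE 0.13, adjusted p = 0.00773). The cytokine gene IL10 fell by 5.10 on the log2 scale (SE 0.30, adjusted p = 0.0120). IL6 was at 10.9 FPKM in the control library, 0.0481 with shRNA 10 and listed at 0 with shRNA 16. PRDM1, a regulator of plasma cell differentiation, fell by 2.67 and BCL3 by 1.12 on the log2 scale, and BCL3 lost its call without the filter on low values (adjusted p = 0.0605). The kinase gene PIM1 rose from 54.6 to 336 ± 22.0 FPKM (SD, n = 2), a log2 change of 2.60 (SE 0.11, adjusted p = 0.00879), and the cyclin gene CCND2 rose by 1.19. Of 32 canonical STAT3 targets measured, 5 rose, 13 fell and 14 did not pass (6 and 13 adjusted over the list alone). Over all tested genes 20.3% were higher and 17.4% lower, so members of this list fell more often than tested genes at large. The list as a whole was not called (median −0.16, mean −0.69, camera adjusted p = 0.313). The list medians lay at percentile 1.7 of matched random lists for shRNA 10 and 15.6 for shRNA 16. Of 31 genes of the JAK-STAT cytokine pathway, 8 rose and 8 fell, with a median of 0.08, a mean of −0.49 and an adjusted p of 0.729. STAT5A rose by 0.97 on the log2 scale, while STAT2, at 14.01 FPKM against 15.8 ± 1.07, and STAT5B, at 9.23 against 7.83 ± 0.819, did not pass (SD, n = 2).

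**Figure D2:**
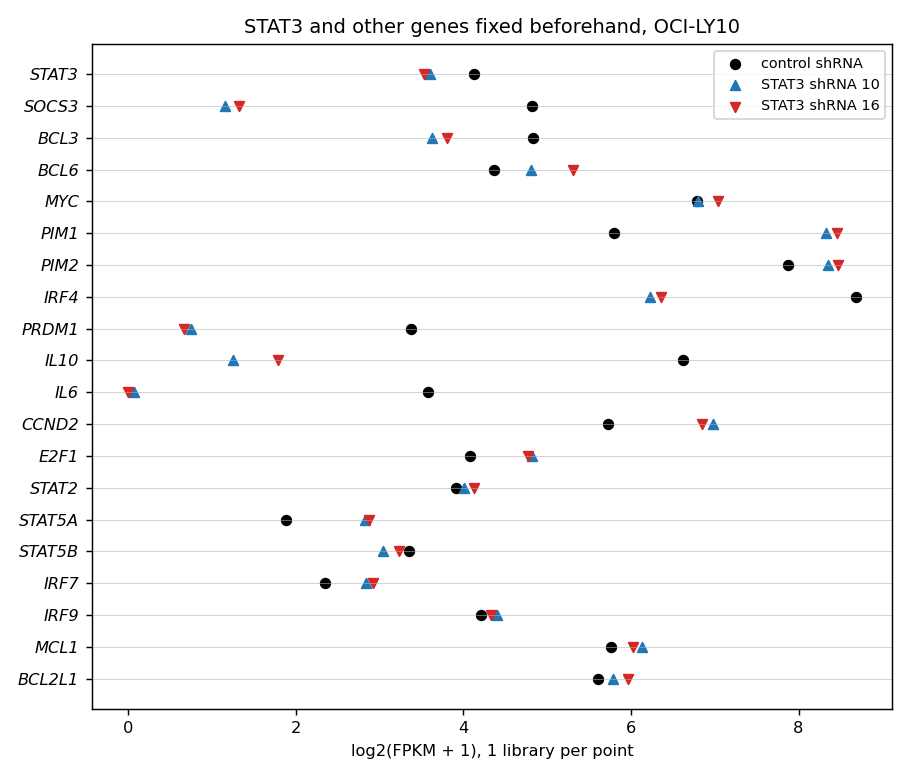
Expression in OCI-LY10 of STAT3 and other genes fixed before the data were examined, as log2(FPKM + 1), with 1 point per library. For SOCS3, IL10, IL6, IRF4 and PRDM1 both STAT3 shRNA libraries (triangles) lie left of the control library (circle), and for PIM1 and CCND2 they lie right of it.

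Other fixed genes of lymphoma biology also differed in direction. IRF4, a transcription factor on which activated B-cell-like lines depend, fell from 411 FPKM to 77.3 ± 4.93 (SD, n = 2), a log2 change of −2.40 (adjusted p = 0.00916). E2F1 rose by 0.71 on the log2 scale (adjusted p = 0.0282). MYC did not pass the test, at 109.9 FPKM in the control library and 120.1 ± 14.04 with the shRNAs (SD, n = 2). BCL6 (adjusted p = 0.161), PIM2 (0.0542), IRF7 (0.0529), IRF9 (0.305), MCL1 (0.106) and BCL2L1 (0.206) did not pass either. IRF7 passed under 6 of the alternative settings, at adjusted p = 0.0432 with quantile normalization, and PIM2 under 3, at 0.0316 with that normalization. BCL6 passed under 1, with genes listed at 0 left out (0.0459).

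Of the 28 gene lists, 3 were called lower in the STAT3 shRNA libraries and 0 higher (camera at the preset inter-gene correlation). At an unadjusted p below 0.05, camera gave 5 lists lower and 3 higher, and fry 5 lower and 4 higher. The higher lists of both tests include T and NK cell markers, with only 2 genes tested. The lower lists of fry include myeloid and erythroid markers, with only 1 gene tested. After adjustment fry called 0 lists in either direction, and camera with an estimated correlation gave 0 lower and 0 higher even at an unadjusted p below 0.05. That estimate rests on 1 residual degree of freedom, and every list had an adjusted p of 0.998 with it. The setting could hardly call any list here, so its lack of calls decides nothing. Fry rests on the same 1 residual degree of freedom, with a lowest adjusted p of 0.144 over the lists, so its lack of calls decides little. The 3 calls rest on camera at the preset correlation alone. Among 17 immediate early genes, which are transcribed within minutes of a stimulus, 11 fell and 0 rose (limma; 12 and 1 adjusted over the list alone, and 12 and 1 at an unadjusted p below 0.05). Examples are ATF3, from 28.1 FPKM to 3.86 and 3.46, FOS, from 7.01 to 0.362 and 0.231, and DUSP2, from 175 to 54.0 and 58.6. The median log2 change of the list was −1.13 (camera adjusted p = 0.000912), with adjusted p = 0.998 with an estimated correlation. Among 30 NF-kB targets, 13 fell and 1 rose (14 and 3 adjusted over the list alone). The chemokine gene CCL22 fell from 43.3 FPKM to 1.87 and 1.62, and TNFAIP2 from 10.9 to 0.593 and 0.747. CCL4 fell by 4.33 and CCL3 fell by 2.74 on the log2 scale, though both have near-identical copies and are uncertain. The median was −0.57 (camera adjusted p = 0.000912), again with adjusted p = 0.998 with an estimated correlation.

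Cytosolic ribosomal protein genes formed the third list called, with 9 of 49 lower and 3 higher. Over all tested genes 17.4% were lower and 20.3% higher, so the list had few higher members rather than many lower ones. RPS15 fell from 3441 FPKM to 781 and 947, and RPS25 rose from 1877 to 4363 and 4828, and both calls were lost without the filter on low values (adjusted p = 0.0549 and 0.0648). Many of these genes have processed copies elsewhere in the genome, so single values are uncertain. Adjusted over the list alone with limma, 0 passed in either direction, while 12 lower and 3 higher had an unadjusted p below 0.05. The median was −0.19 (camera adjusted p = 0.0491), with adjusted p = 0.998 with an estimated correlation and 0.965 after quantile normalization. The call was also lost with a pseudocount of 0.1 FPKM (0.0534), no filter (0.0717), small RNA genes left out (0.0516) and a variance trend in camera (0.0516). Among 41 oxidative phosphorylation genes, 9 fell and 3 rose (8 and 3 adjusted over the list alone). NDUFV2, of respiratory complex I, fell by 1.84 on the log2 scale. That list missed the threshold (median −0.16, adjusted p = 0.0588) but passed it under 4 of the alternative settings, at adjusted p = 0.0223 for genes of mean 5 FPKM or more.

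**Figure D3:**
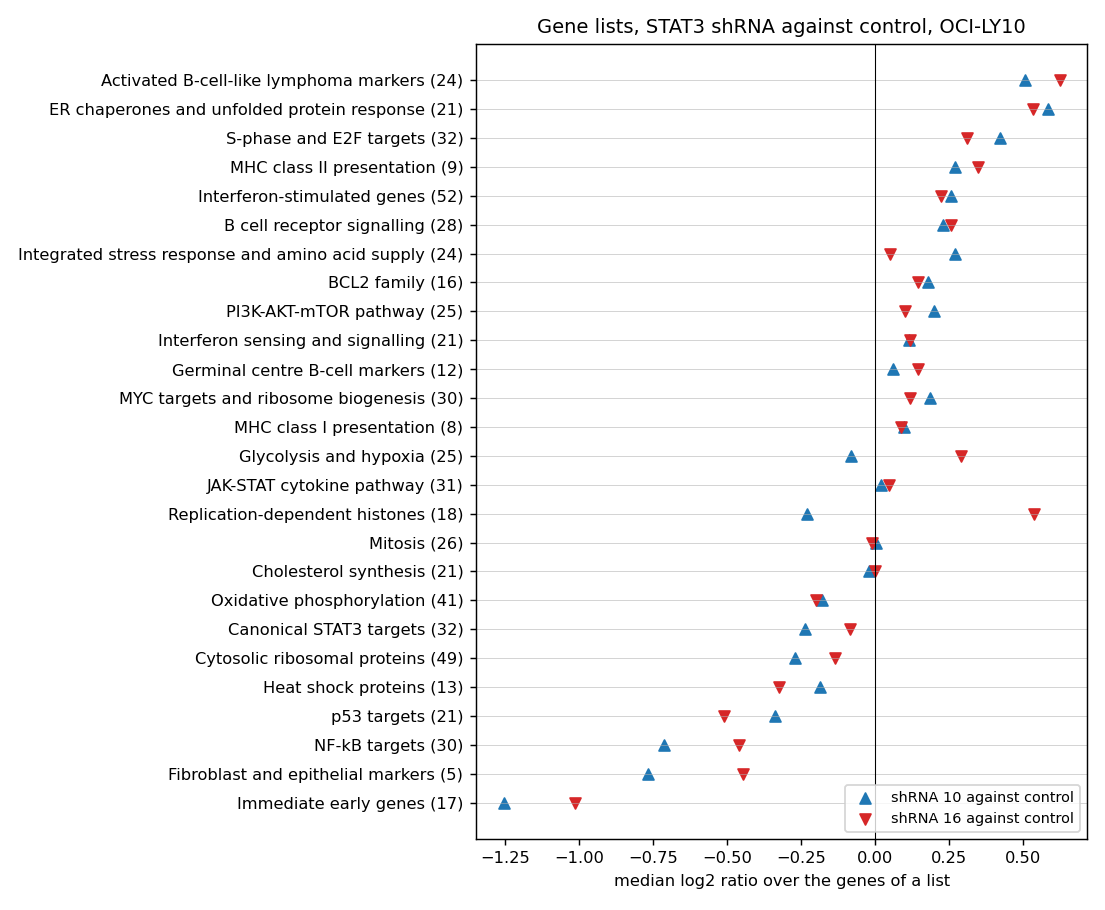
Median log2 ratio to the control library over the tested members of each gene list with at least 5 members, given in brackets, for shRNA 10 and shRNA 16 in OCI-LY10. Immediate early genes lie lowest, at −1.25 and −1.01, and the 2 shRNAs fall on opposite sides of 0 for replication-dependent histones.

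Interferon-stimulated genes, which type I interferon induces, were more often higher than lower without a call for the list. Of 52 measured, 15 rose, 8 fell and 29 did not pass (16 and 8 adjusted over the list alone). ISG20, an exonuclease gene, rose from 12.3 FPKM to 116 and 139.8, and IFIT3, an antiviral effector, from 2.61 to 11.9 and 11.3. LY6E stood at 0.0958 FPKM in the control library against 76.1 and 97.3. In the other direction, IFITM1 was at 34.3 FPKM in the control library and listed at 0 with both shRNAs. The median was 0.24 (camera adjusted p = 0.385), at percentile 93.2 of matched random lists for shRNA 10 and 89.8 for shRNA 16. Of 21 genes of interferon sensing and signalling, 1 rose and 4 fell, among them TLR7, by 1.21 on the log2 scale. Adjusted over the list alone these counts were 1 and 2, and at an unadjusted p below 0.05 they were 5 and 4 (limma). The list had a median of 0.15, a mean of −0.02 and an adjusted p of 0.993.

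Values of genes in the major histocompatibility complex are uncertain in this table. HLA-DRA was listed at 0.0287, 0 and 0 FPKM in the control, shRNA 10 and shRNA 16 libraries, although B2M and CD74, whose products pair with class I and class II molecules, were abundant. B2M stood at 1240 FPKM in the control library and 792 and 808 with the shRNAs, and CD74 at 1195 against 956 and 1061. HLA-C (0.0224 FPKM against 9.47 and 8.54), HLA-DQB1 (0.517 against 14.1 and 17.5) and HLA-DRB5 (7.09 against a listed 0 and 0) are therefore given as values alone. With all HLA genes left out of the count, 2 of 7 class I presentation genes rose and 3 fell, and of 6 class II presentation genes 0 rose and 0 fell. The lists as written, with HLA genes among them, had adjusted p of 0.997 and 0.729. The class I list had a median of 0.09 and a mean of 0.29, while camera placed it on the lower side.

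Genes of B-cell identity and signalling changed widely and in both directions. Among 28 genes of B cell receptor signalling, 10 rose and 7 fell (11 and 8 adjusted over the list alone, list adjusted p = 0.729). CD79B, a signalling chain of the receptor, rose from 226 FPKM to 1139 and 1226, and the phosphatase gene INPP5D from 24.1 to 102 and 100.2. The kinase gene LYN fell from 271 FPKM to 98.1 and 104. Of 24 activated B-cell-like lymphoma markers, 12 rose, including TNFRSF13B, by 1.94 on the log2 scale. A further 7 fell, among them IRF4, PRDM1 and IL10. The median was 0.56, the mean −0.01 and the list adjusted p 0.729. The list medians lay at percentile 99.5 of matched random lists for shRNA 10 and 99.9 for shRNA 16. Of 12 germinal centre B-cell markers, 5 rose and 5 fell. BACH2, a repressor of plasma cell differentiation, was at 0.0833 FPKM in the control library against 13.1 and 15.0, while SERPINA9 was at 29.1 against a listed 0 with both shRNAs. That list had a median of 0.14, a mean of −0.52 and an adjusted p of 0.729.

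Among 21 genes of ER chaperones and the unfolded protein response, 8 rose and 2 fell (13 and 2 adjusted over the list alone). The list medians lay at percentile 99.7 of matched random lists for shRNA 10 and 99.5 for shRNA 16. XBP1, a transcription factor of that response, rose from 20.7 FPKM to 77.5 and 67.4, and EDEM1, of ER-associated degradation, from 17.5 to 46.7 and 47.7. The list missed the threshold (median 0.56, camera adjusted p = 0.0588) and passed it with median-of-ratios scaling (0.0487), a pseudocount of 5 FPKM (0.0352) and no filter on low values (0.0144). Of 32 S-phase genes and E2F targets, 11 rose and 3 fell. E2F2 rose by 3.38 and the chromatin assembly gene CHAF1A by 1.39 on the log2 scale, while TYMS, of thymidylate synthesis, fell by 0.93. The list missed the threshold (median 0.36, adjusted p = 0.0591) and passed it with a pseudocount of 5 FPKM (0.0352) and no filter (0.0144).

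The 2 STAT3 shRNAs were compared with no test, since each has 1 library in this line. At least 1.5-fold, 285 genes were higher and 119 lower with shRNA 16 than with shRNA 10. Outside small RNA genes these counts were 189 and 35. ALDOC, a glycolytic aldolase, was at 7.97 FPKM with shRNA 10, 33.3 with shRNA 16 and 54.7 in the control library. The gene of the vesicle protein SYPL1 was at 21.5 FPKM with shRNA 10 and 8.56 with shRNA 16, against 26.2 in the control library. RAB14, of endosomal transport, was at 25.6 FPKM with shRNA 10, 12.7 with shRNA 16 and 12.8 in the control library. These were chosen after the values were seen, and SNAR-H and C18orf32, higher with shRNA 16, and ST20-MTHFS, lower, changed more and were passed over. Against the control library, the median log2 ratio of 25 glycolysis and hypoxia genes was −0.08 with shRNA 10 (percentile 16.0 of matched random lists) and 0.29 with shRNA 16 (percentile 95.3). That of 18 replication-dependent histone genes was −0.23 (percentile 1.9) and 0.54 (percentile 99.1), and these histone genes have near-identical copies.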

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

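Leaving out small RNA genes, genes listed at 0 or genes in both of 2 lists, and camera with a variance trend, were chosen after seeing the data. No result changed direction past a threshold. Over the main results, 147 of the alternative values stayed close or on the same side of the threshold, 19 moved and 6 lost a call. Over single genes and other lists, 1872 kept their side, 32 gained a call and 41 lost one.

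Without a filter on low values 1299 genes were higher and 2101 lower, and STAT3, at −0.56, lost its call. With a mean of at least 5 FPKM, 1178 genes were lower and 1141 at least 1.5-fold lower with both shRNAs. A pseudocount of 5 FPKM left 1424 genes at least 1.5-fold higher with both shRNAs, and a 2-fold rule left 1180 higher and 1131 lower. With a pseudocount of 0.1 FPKM the STAT3 change was −0.60 and lost its call. Between the STAT3 shRNAs, 507 genes were higher and 201 lower with shRNA 16 at a pseudocount of 0.1 FPKM, and 148 higher at 5 FPKM. Without small RNA genes these were 189 and 35, and without genes listed at 0, 59 were lower. The correlation of the ratios rose to 0.979 without small RNA genes and 0.972 without genes listed at 0. Lists called higher numbered 2 with a pseudocount of 5 FPKM, 2 with no filter and 1 with median-of-ratios scaling. Lists called lower numbered 0 with an estimated correlation and 0 with fry. NF-kB targets had adjusted p = 0.998 with an estimated correlation and 0.147 with fry, and immediate early genes 0.998 and 0.144. Every list had 0.998 with an estimated correlation, which decides nothing at 1 residual degree of freedom. Unless its construction is named here, the cause was not tested.

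Leaving out shRNA 10 or shRNA 16 in turn, with no test, gave 2618 to 2623 genes at least 1.5-fold higher and 2181 to 2243 lower, and a STAT3 change of −0.60 to −0.53. Alternatives that need the TMD8 samples were not run: the fits over both lines, TMD8 alone, the difference between lines, effects per line, and leaving out a TMD8 library. Relabelling over both lines was replaced by the 3 choices of the lone OCI-LY10 library, and leaving out its control leaves no comparison. No paired analysis was possible because each group has 1 library. Absolute depth is unknown, and the control library was 1.52 times as deep as shRNA 10, so low genes are less precisely measured with the shRNAs.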

Other observations

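The tests weighed here on row order, germline-set genes, chromosome-linked genes, the choice of the lone library and heat shock genes were chosen after the result was seen. For heat shock genes, a condition that members must not pass in both directions was added after the value had met the bound first written.

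Members of other fixed lists rose or fell, and none of the lists in this paragraph was called. Of 16 BCL2 family genes, 4 rose and 7 fell, with a median of 0.20, a mean of −0.25 and a list adjusted p of 0.828 (camera). BMF, a pro-apoptotic member, rose from 11.2 FPKM to 78.7 and 91.5, and BCL2A1, a pro-survival member, fell from 367 to 25.8 and 32.6. Of 21 p53 targets, 1 rose and 5 fell (adjusted p = 0.0622), and PHLDA3 was at 3.75 FPKM against a listed 0 with both shRNAs. The medians of the p53 list lay at percentile 1.1 of matched random lists for shRNA 10 and 0.1 for shRNA 16. Of 25 genes of the PI3K-AKT-mTOR pathway, 8 rose and 6 fell (adjusted p = 0.946). Of 24 genes of the integrated stress response and amino acid supply, 6 rose and 5 fell (median 0.21, mean −0.07, adjusted p = 0.997). PHGDH, of serine synthesis, rose from 52.4 FPKM to 184 and 175. Of 21 cholesterol synthesis genes, 5 rose and 2 fell (median −0.01, mean 0.24, adjusted p = 0.997). Adjusted over the cholesterol list alone 6 rose and 5 fell, with 7 and 5 at an unadjusted p below 0.05 (limma). Of 26 mitosis genes 1 rose and 3 fell, and of 30 MYC targets and ribosome biogenesis genes 4 rose and 3 fell, with list adjusted p of 0.993 and 0.729. Adjusted over each of these 2 lists alone, 0 rose and 0 fell. At an unadjusted p below 0.05, 5 mitosis genes were higher and 4 lower, and 6 and 3 of the MYC list (limma). For 25 glycolysis genes the list adjusted p was 0.729, with ENO2 rising by 3.19 on the log2 scale, and for 18 histone genes it was 0.729 (median 0.08, mean −0.06).

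Markers of other cell types were few at 1 FPKM or more. Of 18 T and NK cell markers 2 were measured, CD247 at 0.839 FPKM in the control library against 25.3 and 27.3, and PRF1 at 0.0402 against 7.71 and 10.7 (list adjusted p = 0.107). Of 18 myeloid and erythroid markers 1 was measured, CD68, at 46.6 FPKM against 1.41 and 0.927 (0.281). Of 13 fibroblast and epithelial markers 5 were measured, 2 rising and 2 falling (median −0.61, mean 0.21, 0.796). CDH1 was at 32.6 FPKM in the control library against 0.0102 and a listed 0, the opposite of CDH2.

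Imprinted and cancer-testis genes were listed after some of their values were seen, so their tally is a description. Of the 9 that reached 5 FPKM in a library, 3 met the rule of at most 0.5 FPKM on the other side, against 3.14% of other genes. They are the imprinted gene MEST, at 0.104 FPKM in the control library against 30.8 and 29.0, and the cancer-testis genes MAGEA1, at 0.185 against 80.9 and 64.3, and CTAG2, at 0.110 against 63.3 and 70.2. The other 6 missed it. Among them PEG10 was at 4.81 FPKM against 78.6 and 82.5, PRAME at 115 against 14.2 and 19.3, SGCE at 4.46 against 10.7 and 11.6, and MAGEB1 at 55.0 against 78.3 and 77.9. SNURF was at 0.565 against 119 and 133, but it overlaps SNRPN, and reads of the 2 genes cannot be told apart.

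The largest pattern was the 167 genes seen in the control library alone and the 105 seen in both STAT3 shRNA libraries alone. A slip of control values against shRNA values in the reordered rows would spare rows in alphabetical place. Such rows would then correlate as well with the control library as between the shRNAs, and rows out of place hardly at all. Over 6311 genes in place, however, r was 0.820 between control and shRNA 10 and 0.993 between the shRNAs. Over 4544 genes out of place, r between control and shRNA 10 was 0.864. A slip of names against all 3 libraries together would leave these correlations unchanged, so it was not tested. A 2-day knockdown of STAT3 in one cell population, as the whole cause, would leave the 3 libraries alike in chromosome-linked genes, and 1 did not match. Cells of another origin than the label says were weighed with a separate rule on germline-set genes. It asked for 1 FPKM or more on one side and at most 0.2 on the other, in at least 2 genes. Outside the histocompatibility complex, 1 of 3 usable genes passed these cut-offs (UTS2, 3.25 FPKM against a listed 0). GSTM1 (31.4 against 3.99 and 4.97) and ERAP2 (1.35 against 0.933 and 0.855) did not. The rule as first written also counted HLA-DRB5, which made 2 genes and met its bound. Another line, a mislabelled sample or a diverged subclone may each account for the pattern and cannot be told apart here, nor can the side that is out of place from the 3 libraries analysed, and a contribution of STAT3 depletion stays open.

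The count of genes past the threshold was 4206 with the control as the lone library, and the highest with another library in its place was 0, with 62 and 61 genes at an unadjusted p below 0.05 (limma). Of the 3 choices, 1 gave as many genes, and 3 choices are too few for a share under 0.05. With an shRNA library as the lone one, the control counts as a replicate of the other shRNA, so the gap already described enters the spread and a low count was to be expected.

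Immediate early genes and NF-kB targets were called lower in the shRNA libraries by camera at the preset correlation only. With an estimated correlation both had adjusted p = 0.998, as did every other list, and with fry 0.144 and 0.147. At 1 residual degree of freedom the setting with an estimated correlation decides nothing, and fry decides little. Handling stress that raised immediate early and heat shock genes together would lower heat shock genes as well. Their median was −0.26, at percentiles 8.8 and 2.9 of matched random lists for shRNA 10 and shRNA 16, and lay 0.88 above that of immediate early genes on the log2 scale. Of 13 heat shock genes, 3 were higher and 1 lower, with 3 and 4 at an unadjusted p below 0.05 (list adjusted p = 0.543). A median over members that go both ways decides nothing, so handling stress stays open. STAT3 depletion, or the wider difference of the control library, may underlie the pattern, and neither was tested apart from the other.

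Genes at 20 FPKM or more and at least 8-fold apart had a median residual level of 2.49% on the low side for 109 genes high in the control library and 3.73% for 64 genes high in the shRNA libraries. These values were taken to weigh a mixture of cell populations. Choosing genes at least 8-fold apart limits the residual level in advance, so a low median decides nothing on a mixture. Of 161 small RNA genes seen in both shRNA libraries, 43.5% had a ratio on 1-read steps (within 1%), against 5.8% of 10740 longer genes. The share of small RNA genes fell short of the bound set for few reads as the cause. The bound set against that cause, a share no higher than that of longer genes, was not met either. Few reads as the cause therefore stayed undecided. Both comparisons in this paragraph were chosen after the result was seen.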
